A study of Danio rerio with 8 samples.

How the data were processed

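Gene expression was measured on Affymetrix zebrafish arrays in 8 samples, the 4 sorted cell populations of 2 transplanted embryonal rhabdomyosarcomas. Per the labels, the tumours came from fish injected with an activated kras transgene under the rag2 promoter, carried a GFP reporter driven by myf5 and an mCherry reporter driven by mylz2 (now named mylpfa), and were grown in recipient fish. The cells were sorted by flow cytometry in repeated rounds before total RNA was amplified with the NuGEN Ovation Pico WTA system and labelled with biotin. The deposited table holds log-scale values for 15502 probe sets, read here as log2. The base of the logarithm, the method that summarised the probes and the scaling between arrays are not given in the sources used here. The values run from 0 to 12.79 with array medians between 4.54 and 4.71, which excludes a linear scale. Base 2 is the usual choice for such tables, but a natural logarithm is not excluded by the values. Folds would then be larger, while the limma p-values would be the same. Between 14 and 25 values per array are exactly 0, and no pair of arrays shared more than 0.68% of its values. Array quality values and signal over background were not used here, and the number of arrays limits the precision.

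The group of each array and its tumour number were taken from the labels. The arrays of one tumour number come from the same tumour, so the numbers pair the populations. As a check, the correlation across probe sets between the deviations of same-numbered arrays from their population means was computed for each pair of populations. It was 0.0974 for GFP-only with double-positive, 0.402 for GFP-only with mCherry-only, 0.492 for GFP-only with double-negative, 0.199 for double-positive with mCherry-only, -0.0291 for double-positive with double-negative and 0.481 for mCherry-only with double-negative. The fit without the tumour gave the reported values, and the fit with the tumour as a block was run beside it.

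Probe sets were named from the reference table of the array's annotation, with symbols updated to current RefSeq names through gene identifiers. Of the 15502 probe sets, 10795 had 1 gene symbol, 135 had several and 4572 had none in that table. Names were used only for the probe sets with 1 symbol, which cover 8793 genes. Of these probe sets, 10711 had an identifier in the RefSeq table, and 1 symbol was updated. The 1539 genes with more than 1 probe set are represented by the one with the highest mean over all 8 arrays. Genes of multigene families such as parvalbumins, troponins, myosins, globins and trypsins have close copies, and their probe sets could read more than 1 of them.

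Values were used as deposited. A linear model of 4 population means was fitted to all 8 arrays with lmFit and eBayes in limma 3.58.1 (R 4.3.3), which leaves 4 residual degrees of freedom. The prior had 6.07 degrees of freedom and a standard deviation of 0.643. With the tumour as a block, the residual degrees of freedom were 3, the prior had 6.81 and its standard deviation was 0.552. The tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all probe sets within each of 8 comparisons, with a threshold of 0.05. The 8 comparisons were the 6 pairs of populations, GFP-only against the mean of the other 3 populations, and the interaction of both reporters. Errors of differences are limma's standard errors, and errors of levels are standard deviations over 2 tumours. The reported p-values measure the spread between the 2 arrays of each population, pooled over the populations. They treat the 8 arrays as independent, although the tumour numbers pair the populations. Only the fit with the block takes that pairing into account.

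Gene lists were fixed before the data were examined. They cover myogenic progenitor, myogenic commitment and fusion, fast muscle sarcomere, slow and cardiac muscle, cell cycle, RAS-MAPK response, Notch pathway, Wnt and hedgehog response, oxidative phosphorylation and TCA cycle, glycolysis, ribosomal protein, and heat shock and dissociation stress genes. Lists for other cell types hold fibroblast and matrix, endothelial, myeloid, lymphocyte, erythroid and thrombocyte, epithelial and skin, liver, pancreas and gut, and neural and glial genes. The 20 lists were tested with camera (limma), which compares a list's members with all other genes, at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data. Adjustment was over the 20 lists within a comparison. Listed symbols were matched to current symbols, and through synonyms only where the listed symbol is no current gene. That limit on synonyms was set after values had been seen, because unlimited matching had put wrong genes in lists (ezh2 for eya2, for example). The fixed rule for ribosomal protein genes also takes rps6k kinases and rps19bp1, and the lymphocyte list holds polr1g, an RNA polymerase subunit that was listed under its older symbol cd3eap.

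The genes named in the text follow a rule fixed before the data were examined. It takes myf5, mylpfa, myod1, myog, desma, cdh15, pax7a, pax3a and met in every comparison. In the comparisons of GFP-only with each other population it takes the 10 largest called differences in each direction, and in the others the 5 largest, always with the same sign in both tumours. Where fewer than 5 were called in a direction of the former, the largest differences at an unadjusted p under 0.01 fill up to 5 as values only. For each list it takes up to 4 called members, or otherwise the 2 largest differences as values only. Genes known only by clone names were counted but not named. Genes outside this rule are said to be so where they appear.

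The fits were tested on simulated data for the comparison of GFP-only with mCherry-only, over 15502 probe sets of which 50 were changed at each of 4 sizes. Without the block, 3 of 50 were recovered at a log2 difference of 2, 14 at 3, 29 at 4 and 49 at 6, with 3 unchanged probe sets among 98 called. With the block, run on other simulated data with an added tumour shift, the numbers were 0, 13, 29 and 48. As the data differed, these runs do not compare the power of the fits. Both gave every array the same spread for a probe set, which the real arrays need not have. The list test, run 20 times on 4000 simulated genes, called the shifted list in 20 runs and 0 of 380 unshifted lists. These genes were simulated independently of each other. The run therefore does not measure false calls for lists whose genes vary together.

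Alternatives were the tumour as a block, only the arrays of the populations compared, quantile normalization, leaving out the 30% of probe sets with the lowest mean, a mean-variance trend in eBayes, a minimum fold of 2, leaving out each array in turn, and for lists the estimated correlation and the mean of all probe sets of a gene. A pseudocount was not needed, since the values are already on a log scale. Leaving out the mCherry-only and double-negative arrays of tumour 2 together was added after the data had been seen. Where an arm was left with 1 array, that array was assumed to vary like the other populations. Leaving out an array of a population outside a comparison does not change the difference. Such a run changes only the estimated spread and its degrees of freedom. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The reverse-transcription PCR and the transplantation assays that the study's design mentions were not analysed here.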

Results

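Expression was profiled in cells of zebrafish embryonal rhabdomyosarcoma, a tumour with features of developing skeletal muscle, sorted by 2 fluorescent reporters. The myf5 promoter, active in early myogenic cells, drives GFP, and the mylz2 promoter, active in differentiated fast muscle, drives mCherry. Each of 2 tumours gave 4 populations: GFP-only, double-positive, mCherry-only and double-negative, so that each population has 2 arrays (n = 2 tumours). The study's design asks whether the GFP-high fraction is molecularly distinct from the other tumour cell subtypes. Values are deposited log-scale signals, read as log2. The base is not stated, and with a natural logarithm the folds would be larger. Signal over background was not measured, and the low side of several large differences lies under the lower quartile of its arrays (for example lgals3bp.1 at 2.66 in GFP-only and cyp26a1 at 1.76 in mCherry-only cells), so no folds are given. A difference is the first population minus the second, with limma's standard error (SE), and n = 2 arrays per population throughout.

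The array values separated tumours about as much as populations. The median absolute difference between the tumours was 0.65 in GFP-only, 0.56 in double-positive, 0.68 in mCherry-only and 0.84 in double-negative cells. Between populations of the same tumour it lay between 0.40 (GFP-only against double-negative cells of tumour 1) and 0.82. The mCherry-only and double-negative arrays of tumour 2 stood apart: their mean rank correlation with the GFP-only and double-positive arrays was 0.648 and 0.653, against 0.805 and 0.849 for the same populations of tumour 1. On these arrays the myogenic commitment list was also lower than in tumour 1, by a median difference of -1.70 in mCherry-only and -1.37 in double-negative cells, and the erythroid list was higher by 0.64 and 0.84. In GFP-only and double-positive cells the commitment list was lower by -0.51 and -0.66 and the erythroid list higher by 0.33 and 0.16.

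The reporter genes were read first. The mylz2 gene mylpfa, a fast muscle myosin light chain, had mean values of 10.79 ± 0.11 (SD) in double-positive and 10.01 ± 1.12 in mCherry-only cells, above 6.82 ± 0.83 in GFP-only and 4.66 ± 0.11 in double-negative cells. It was higher in double-positive than in double-negative cells (6.14 ± 0.67, adjusted p = 0.00499) and higher in mCherry-only than in double-negative cells (5.35 ± 0.67, adjusted p = 0.0122). Between GFP-only and mCherry-only cells its difference of -3.19 ± 0.67 had an adjusted p of 0.0734, and 0.0263 with the tumour as a block. Between GFP-only and double-positive cells the difference was -3.98 ± 0.67 (adjusted p = 0.175, blocked 0.0462). A second mylpfa probe set gave -3.70 and -4.69 in these comparisons, with adjusted p-values of 0.324 and 1. Against double-negative cells that probe set differed by 6.83 in double-positive and 5.84 in mCherry-only cells, with adjusted p-values of 0.0578 and 0.135. Without either double-positive array mylpfa was no longer called against double-negative cells, in mCherry-only cells also without the mCherry-only array of tumour 1 or the double-negative array of tumour 2 (adjusted p up to 0.128 and 0.0884). Transcripts of myf5, a myogenic determination factor, were at 5.34 ± 0.18 in GFP-only, 4.92 ± 1.56 in double-positive, 3.81 ± 0.75 in mCherry-only and 4.02 ± 0.08 in double-negative cells. No comparison of myf5 passed the test, and the smallest adjusted p was 0.476, for a GFP-only minus mCherry-only difference of 1.53 ± 0.74 (1.00 without the mCherry-only array of tumour 1). The other muscle regulators and markers fixed in advance, myod1, myog, desma, cdh15, pax7a, pax3a and met, passed the test in 0 comparisons by limma, with or without the block. Of these, cdh15, the muscle cadherin, had GFP-only differences of 2.98 to mCherry-only and 3.39 to double-negative cells at unadjusted p-values of 0.0444 and 0.0260. These fell to 1.55 and 1.22 without the mCherry-only and the double-negative array of tumour 2, respectively, and the latter rose to 5.56 and was called without the double-negative array of tumour 1. The probe sets of pax7a differed in sign.

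**Figure D1:**
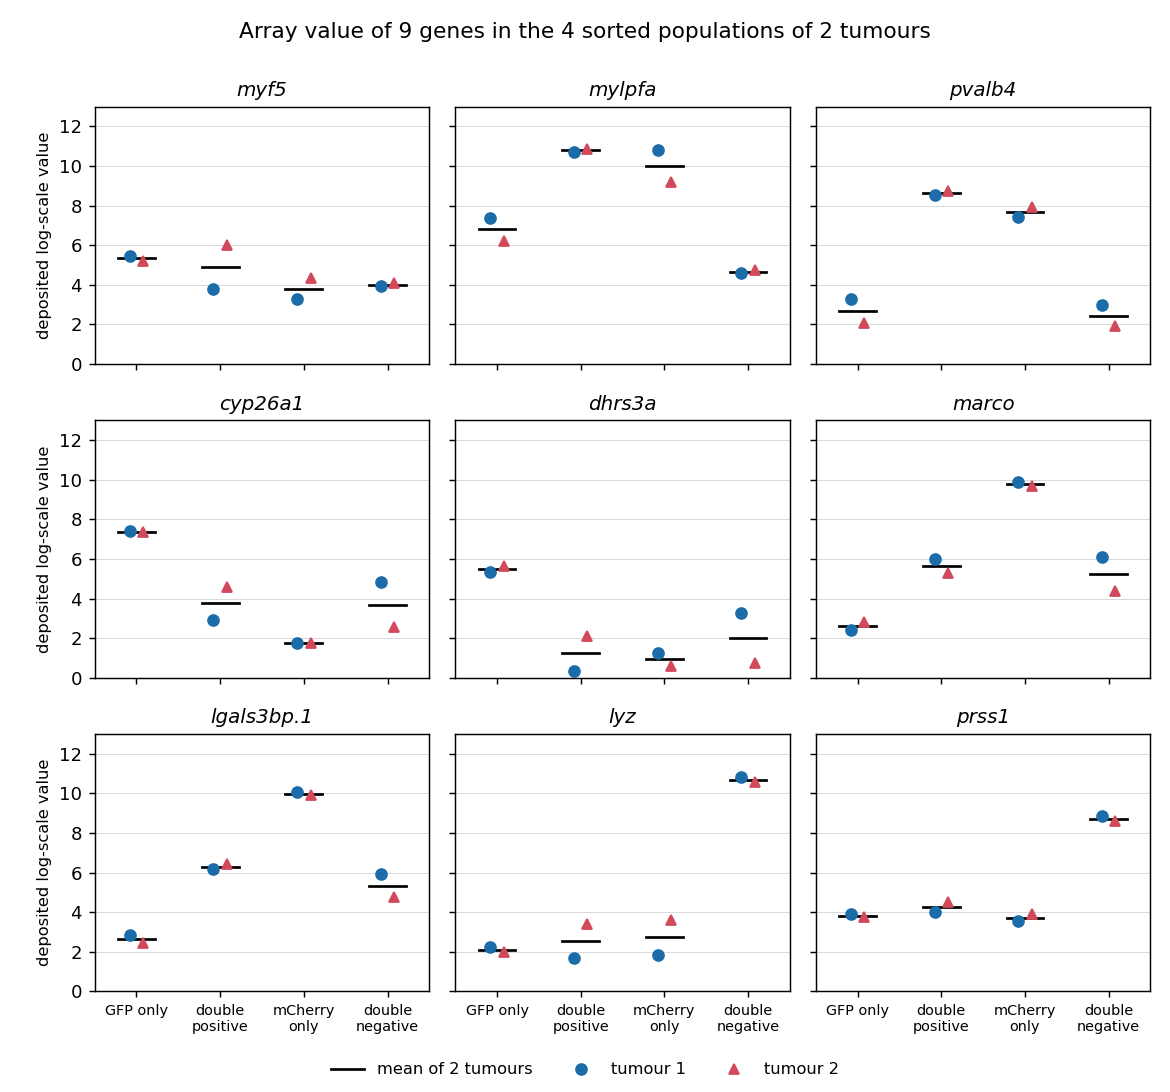
Deposited log-scale value (vertical axis) of 9 genes in the 4 sorted populations (horizontal axis), with 1 point per tumour and a line at the mean of 2 tumours. Values of mylpfa lie at 10.71 and 10.87 in double-positive cells and at 4.58 and 4.73 in double-negative cells, and cyp26a1 lies at 7.43 and 7.34 in GFP-only cells and at 1.75 and 1.76 in mCherry-only cells.

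GFP-only cells were compared with mCherry-only cells to separate cells with the early reporter from those with the differentiation reporter alone. Macrophage genes were lower in GFP-only cells: lgals3bp.1, a secreted scavenger-receptor-domain protein, by a log2 difference of -7.34 ± 0.57, marco, a macrophage scavenger receptor, by -7.17 ± 0.66, and c1qc, a chain of complement C1q, by -6.59 ± 0.68. Genes of fast muscle fibres were lower as well, among them the calcium-buffering parvalbumins pvalb4 (-4.99 ± 0.63) and pvalb2 (-4.98 ± 0.86) and the tropomyosin tpma (-4.43 ± 0.69). The retinoic acid hydroxylase gene cyp26a1 was higher in GFP-only cells by 5.63 ± 0.81, and dhrs3a, which codes for a retinaldehyde reductase, by 4.59 ± 0.86. The remaining largest decreases were in scinlb (-6.35), an actin-severing scinderin, the globin hbaa1 (-6.19), rgs2, fgl2a, the amino acid transporter slc7a7, the integrin itgae.2 and the cathepsin ctss2.2, between -6.05 and -5.89. All of these had the same sign in both tumours.

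By cell type, 17 of 29 measured myeloid genes were lower in GFP-only than in mCherry-only cells and 0 higher, or 20 lower and 1 higher when adjusted over the list alone. Camera gave the list an adjusted p of 9.51e-29, with a median difference of -4.66. It stayed called at adjusted p = 0.0421 with an estimated correlation, but not with the tumour as a block as well (0.195). Of 20 erythroid and thrombocyte genes 1, hbaa1, was lower (3 adjusted over the list alone; camera adjusted p = 0.000382, adjusted p = 0.362 with an estimated correlation). The endothelial list (median -0.74, adjusted p = 0.0409) and the liver, pancreas and gut list (median -0.39, adjusted p = 0.0242) were lower by camera with 0 members called by limma, 1 of 13 and 1 of 36 being lower and 1 endothelial gene higher at an unadjusted p under 0.05. They had adjusted p = 0.448 and 0.554 with an estimated correlation, and 1 endothelial gene was lower when adjusted over the list alone. The endothelial list lost its call without the GFP-only array of tumour 1, the mCherry-only array of tumour 2 or either double-negative array (adjusted p from 0.0519 to 0.375), and the liver, pancreas and gut list without the GFP-only array of tumour 1 (0.378) or the mCherry-only array of tumour 2 (0.176). The largest endothelial differences were -2.48 in mrc1a and 2.17 in cd34 (1.41 without the mCherry-only array of tumour 2), and those of the liver, pancreas and gut list were -3.71 in fgg and -1.75 in cpa4 (-0.88 without the GFP-only array of tumour 1), whose other probe set had the opposite sign. The fgg value came from the mCherry-only array of tumour 2 (10.86, against 2.81 in tumour 1), and without it the difference was 0.32 (without that of tumour 1, fgg was called). The calls of the endothelial and liver lists were also lost with quantile normalization (adjusted p = 0.0720 and 0.108), and that of the endothelial list without the dimmest 30% of probe sets (0.133). Both ended as well without the pair of tumour 2 arrays that stood apart (adjusted p = 0.163 for each). The liver median was -0.78 without the mCherry-only array of tumour 1 and -0.73 without the GFP-only array of tumour 2.

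Among the muscle programs, 5 of 38 fast muscle sarcomere genes were lower in GFP-only cells, or 9 when adjusted over the list alone. The list's median difference was -1.37 (camera adjusted p = 4.08e-10; adjusted p = 0.362 with an estimated correlation), and -0.65 and -2.06 without the mCherry-only array of tumour 1 or 2. The calls of pvalb2 and pvalb1 were lost without either double-positive array, the mCherry-only array of tumour 1 or the GFP-only array of tumour 2 (adjusted p up to 0.217 and 0.192). That of tpma was lost without either GFP-only array or the mCherry-only array of tumour 1 (up to 0.137), and that of pvalb4 without the GFP-only or mCherry-only array of tumour 2 (0.0638 and 0.0604). The glycolytic enzyme pfkma, a muscle phosphofructokinase, was lower by -3.25 ± 0.62 (adjusted p = 0.0467) and was the 1 called member of 24 glycolysis genes (2 lower adjusted over the list alone), a list that camera did not call (adjusted p = 0.253, and 0.0213 without the pair of tumour 2 arrays that stood apart). It stayed called only without either double-negative array, with an adjusted p up to 0.293 in the other runs that left out 1 array. In the myogenic progenitor list 1 of 17 genes was lower, cxcr4b (-5.80 ± 0.54, adjusted p = 0.00152), a chemokine receptor that leukocytes also express, and camera did not call the list (adjusted p = 0.398). The commitment and fusion list (adjusted p = 0.172) and the slow and cardiac list (adjusted p = 0.172) had 0 members called by limma and 0 at an unadjusted p under 0.05. Their largest differences were 2.64 in jam2a and -2.17 in tnnc1a, which fell to 1.06 without the mCherry-only array of tumour 2 and to -0.37 without the GFP-only array of tumour 1.

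Growth and signalling lists were higher in GFP-only cells by camera, with 0 members called by limma in each. The cell cycle list had a median difference of 0.81 over 53 genes (adjusted p = 3.53e-05; adjusted p = 0.362 with an estimated correlation), with 14 genes higher at an unadjusted p under 0.05 and values of 3.19 for lmnb2 (1.94 without the mCherry-only array of tumour 2) and 2.35 for rpa2. The ribosomal protein list had a median of 0.73 over 78 genes (adjusted p = 2.74e-07; adjusted p = 0.554 with an estimated correlation; 3 higher at an unadjusted p under 0.05), led by rpl7l1 at 1.79 (1.16 without that array). The oxidative phosphorylation and TCA cycle list had a median of 0.54 over 60 genes (adjusted p = 0.000483; adjusted p = 0.578 with an estimated correlation; 4 higher at an unadjusted p under 0.05), led by idh3b at 2.98, whose other probe set was at 0.04. The RAS-MAPK response list had a median of 0.98 over 27 genes (adjusted p = 0.0103; adjusted p = 0.554 with an estimated correlation), and 7 of its genes were higher and 1 lower at an unadjusted p under 0.05, with 2.90 for mycb. The Notch pathway list had a median of 0.49 over 27 genes (adjusted p = 0.00974; adjusted p = 0.303 with an estimated correlation) and 7 higher at an unadjusted p under 0.05. Adjusted over the list alone, 1 RAS-MAPK gene and 3 Notch genes were higher. Without the mCherry-only array of tumour 2 the ribosomal, oxidative phosphorylation and RAS-MAPK lists lost their calls (adjusted p = 0.143, 0.353 and 0.0595), and without that of tumour 1 the Notch list did (0.0641). The ribosomal and oxidative phosphorylation medians were 0.21 and 0.22 in the former run and 1.21 and 0.91 in the latter, and both calls also ended without the pair of tumour 2 arrays that stood apart (adjusted p = 0.163 and 0.322). The transcriptional repressor her6 of the Notch list had the largest value, 6.08 ± 1.47 (adjusted p = 0.126, blocked 0.0697, and 0.00405 with only the arrays compared), and hey1 was at 3.08.

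The other lists were not called by camera in this comparison. These were the Wnt and hedgehog (adjusted p = 0.929), heat shock and dissociation stress (0.692), fibroblast and matrix (0.183), lymphocyte (0.387), epithelial and skin (0.515) and neural and glial (0.178) genes. They had 0 members called by limma, and between 1 and 6 members of each had an unadjusted p under 0.05. Adjusted over the list alone, 1 heat shock and 1 lymphocyte gene were lower. The median and mean of the Wnt and hedgehog, heat shock and epithelial lists had opposite signs. The largest values in these lists were 3.95 for the matrix gene sparc, 4.00 for the keratin krt15, -2.25 for the lymphoid factor ikzf1, -1.98 for nkx2.2a and 1.89 for tubb5. The stress chaperone hsp90aa1.2, at -2.73 ± 0.57, had an adjusted p of 0.0725, and 0.0298 with the block, while its other probe set was lower by -3.98 (adjusted p = 0.0212). The chaperone hspd1 was at 3.40, but at 1.43 without the mCherry-only array of tumour 2 and 5.37 (adjusted p = 0.0172) without that of tumour 1. The values of fat1a (5.46) and cygb1 (4.23) did not pass, with adjusted p-values of 0.151 and 0.230, and 0.0967 and 0.0777 with the block. They fell to 2.86 without the GFP-only array and 2.44 without the mCherry-only array of tumour 2, respectively.

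In all, limma called 133 probe sets between GFP-only and mCherry-only cells, 3 higher and 130 lower, which name 97 genes. Besides cyp26a1 and dhrs3a, 1 probe set without a gene name was higher. At an unadjusted p under 0.05, 912 probe sets were higher and 832 lower. The block for the tumour raised the calls to 248, 18 higher and 230 lower. The count was 54 and 43 without the GFP-only array of tumour 1 or 2 and 45 without the mCherry-only array of tumour 2. The few higher calls depend on the arrays used: 21 were higher with only the arrays compared, 30 without either double-negative array, 14 without the mCherry-only array of tumour 1 and 0 without the GFP-only or mCherry-only array of tumour 2. Without any 1 of the 4 GFP-only and mCherry-only arrays, cyp26a1 was no longer called (adjusted p between 0.0502 and 0.0821), and dhrs3a stayed called only without either double-negative array (adjusted p from 0.0698 upward in the other runs).

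GFP-only cells were next compared with cells that carry neither reporter. Genes of the myeloid and erythroid lists were lower in GFP-only cells, as was scinlb: lyz, the lysozyme of phagocytes, by -8.59 ± 0.75, the globin hbaa1 by -7.82 ± 0.73, scinlb itself by -7.61 ± 0.57, and nt5c2l1, a nucleotidase-like gene of the erythroid list, by -6.26 ± 0.60. Myeloid-list genes of the actin cytoskeleton and granules followed, with coro1a at -5.93 ± 0.63, the proteoglycan srgn at -5.91 ± 0.67 and the plastin lcp1 at -5.80 ± 0.76. Outside that list, susd3, wasb and capgb lay between -5.51 and -5.33. A second probe set of coro1a differed by only -0.61. Digestive enzymes of the exocrine pancreas were lower as well, among them the trypsin gene prss1 (-4.92 ± 0.52), the chymotrypsin genes ctrb.1 (-3.92 ± 0.66) and ctrl (-3.61 ± 0.60), and the amylase gene amy2a (-3.10 ± 0.54). With all arrays 0 probe sets were called higher in GFP-only cells by limma (299 at an unadjusted p under 0.05), but 81 were without the double-negative array of tumour 1.

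Of 29 myeloid genes, 8 were lower in GFP-only than in double-negative cells (18 adjusted over the list alone), with a median difference of -2.31 and a camera adjusted p of 2.47e-32. The list kept its call at adjusted p = 0.0336 with an estimated correlation, but not with the block as well (0.0811). Of 20 erythroid and thrombocyte genes 5 were lower (10 adjusted over the list alone), including the erythroid transcription factor klf1 (-4.14 ± 0.73) and the heme synthesis enzyme alas2 (-3.75 ± 0.57). The list's median was -2.25 (adjusted p = 9.00e-20; adjusted p = 0.0596 with an estimated correlation). Of 36 liver, pancreas and gut genes 4 were lower (10 adjusted over the list alone; camera adjusted p = 1.00e-10, adjusted p = 0.140 with an estimated correlation). Of 9 lymphocyte genes 1, ikzf1 (-4.00 ± 0.57), was lower (2 adjusted over the list alone; camera adjusted p = 0.00259, adjusted p = 0.140 with an estimated correlation). The chemokine receptor cxcr4b, in the myogenic progenitor list, was lower by -4.46 ± 0.54 and was the 1 member called of 17 (2 adjusted over the list alone). Without the GFP-only array of tumour 2, srgn, prss1 and susd3 (adjusted p = 0.0580), wasb, capgb and cxcr4b (0.0719) and lcp1 (0.109) were no longer called, and capgb also not without that of tumour 1. The erythroid genes klf1 and alas2, ikzf1, and the enzymes ctrb.1 and ctrl kept their calls in 1, 3, 3, 2 and 2 of the 8 runs that left out 1 array, and amy2a in 0 (adjusted p up to 0.365, 0.230, 0.176, 0.258, 0.298 and 0.326). Each of these 6 was lost without either GFP-only array and without the double-negative array of tumour 2.

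The fast muscle and the commitment and fusion lists were higher in GFP-only than in double-negative cells by camera, with 0 members called by limma. Camera did not call the myogenic progenitor and the slow and cardiac lists. The fast muscle list had a median of 1.34 (adjusted p = 2.93e-09; adjusted p = 0.323 with an estimated correlation) and 14 of 38 genes higher at an unadjusted p under 0.05, led by actc1b at 3.33 (1.70 without the double-negative array of tumour 2, and 3.26, 0.20 and 0.83 on its other probe sets) and mylz3 at 3.04 ± 0.82. The latter had an adjusted p of 0.326, and 0.0244 with the block. All 14 commitment and fusion genes had positive differences (median 1.45, adjusted p = 5.08e-05; adjusted p = 0.355 with an estimated correlation), with 1 higher at an unadjusted p under 0.05. That median was 0.59 without the double-negative array of tumour 2 (adjusted p = 0.0454), 2.23 without that of tumour 1 and 0.86 without the GFP-only array of tumour 1. The RAS-MAPK response (mean 0.93), oxidative phosphorylation (median 0.62) and heat shock lists (median 0.58) were higher, with camera adjusted p-values of 0.000211, 1.26e-06 and 0.00259 and 2, 2 and 6 genes higher and 1, 0 and 1 lower at an unadjusted p under 0.05. They had adjusted p = 0.388, 0.494 and 0.479 with an estimated correlation. The neural and glial list was lower (median -0.29, adjusted p = 0.00595; adjusted p = 0.494 with an estimated correlation), with 1 gene lower and 1 higher at an unadjusted p under 0.05. Without the double-negative array of tumour 2 the RAS-MAPK, oxidative phosphorylation, heat shock and neural lists lost their calls (adjusted p = 0.413, 0.119, 0.151 and 0.655), the latter 2 also without the GFP-only array of tumour 1 (0.169 and 0.439). These 4 calls ended as well without the pair of tumour 2 arrays that stood apart (0.460, 0.102, 0.154 and 0.608). The oxidative phosphorylation median was 0.20 without the double-negative array of tumour 2 and 1.05 without that of tumour 1. Without the double-negative array of tumour 2 or the GFP-only array of tumour 1 the median of the neural list turned positive (0.04 and 0.02), so its direction rests on these arrays, and its call was also lost without the dimmest 30% of probe sets (0.0766). The endothelial list, not called here (adjusted p = 0.0682), was lower by camera with the mean of all probe sets of a gene (0.00816). The retinoid genes cyp26a1 (3.70 ± 0.81) and dhrs3a (3.52 ± 0.86, and 2.25 without the double-negative array of tumour 2) did not pass, with adjusted p-values of 0.129 and 0.220, and 0.0867 and 0.143 with the block.

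The limma fit called 80 probe sets between GFP-only and double-negative cells, 0 higher and 80 lower, which name 61 genes. At an unadjusted p under 0.05, 299 were higher and 462 lower. A block for the tumour gave 121 calls, 3 higher and 118 lower. The count fell to 28 and 11 without the GFP-only array of tumour 1 or 2, to 34 without either double-positive array and to 38 without the double-negative array of tumour 2, and was 174, 81 higher and 93 lower, without that of tumour 1. It was 18 with only the arrays compared and 46 without the 2 arrays of tumour 2 that stood apart, where klf1, alas2, ctrb.1, ctrl and amy2a were no longer called (adjusted p between 0.0693 and 0.220).

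Between GFP-only and double-positive cells, which differ in the mCherry reporter, fast muscle genes had the largest differences. The parvalbumin pvalb4 was lower in GFP-only cells by -5.94 ± 0.63 (adjusted p = 0.0395) and was the 1 probe set that passed. The next values were -5.49 ± 0.86 for pvalb2, -5.27 ± 0.71 for pvalb1, -5.07 ± 0.69 for tpma and -4.78 ± 0.72 for the troponin tnni2a.4. These had adjusted p-values of 0.135, 0.115, 0.115 and 0.135, and 0.0140, 0.0108, 0.0277 and 0.0277 with the tumour as a block. The muscle phosphofructokinase gene pfkma was at -4.14 ± 0.62 (adjusted p = 0.135, blocked 0.0444).

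Of 38 fast muscle sarcomere genes, 1 was lower over all probe sets tested and 22 were lower when adjusted over the list alone. The list's median was -2.65 (camera adjusted p = 2.74e-54; adjusted p = 0.0932 with an estimated correlation), and 37 of 38 members had negative differences. The commitment and fusion list was lower (median -0.60, adjusted p = 0.0320; adjusted p = 0.661 with an estimated correlation) with 0 members called by limma and 0 at an unadjusted p under 0.05. The myeloid list was lower too (median -0.75, adjusted p = 4.58e-13; adjusted p = 0.0947 with an estimated correlation), with 0 of 29 members called by limma, 4 lower when adjusted over the list alone and 10 lower at an unadjusted p under 0.05. Its largest value was -3.64 ± 0.57 in lgals3bp.1 (adjusted p = 0.135, blocked 0.0426). The cell cycle list was higher in GFP-only cells (median 0.50, adjusted p = 3.64e-07; adjusted p = 0.329 with an estimated correlation), with 0 of 53 called and 1 at an unadjusted p under 0.05, the helicase subunit mcm4 (2.14). Its median was 0.24 and 0.85 without the double-positive array of tumour 1 or 2. The ribosomal list was also higher (median 0.18, adjusted p = 0.0320; adjusted p = 0.748 with an estimated correlation), with 0 members at an unadjusted p under 0.05. The commitment list lost its call without the double-positive array of tumour 1 (adjusted p = 0.981) or the GFP-only array of tumour 2 (0.516), and the ribosomal list without the GFP-only array of tumour 1 (0.595) or the double-positive array of tumour 2 (0.562). The erythroid list, not called (adjusted p = 0.0611), was lower by camera without the dimmest 30% of probe sets (0.0105). In the higher direction dhrs3a (4.29), cyp26a1 (3.63), bmb (2.75), mcm4 and cfap20 (2.11, but 1.31 without the GFP-only array of tumour 2) had the largest values, and their adjusted p-values lay between 0.408 and 1, and between 0.192 and 0.739 with the block. With only the arrays compared dhrs3a passed (adjusted p = 0.0327), as did pvalb2, pvalb1, tpma, tnni2a.4, pfkma, lgals3bp.1 and mylpfa (adjusted p up to 0.0327).

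In total 1 probe set was called by limma between GFP-only and double-positive cells, and 18, all lower, with the tumour as a block. At an unadjusted p under 0.05, 105 were higher and 221 lower. The call of pvalb4 was lost with quantile normalization (adjusted p = 0.119) and without any 1 of the 6 arrays other than the double-negative ones (adjusted p from 0.0590 to 1). The count was 3 without either double-negative array, and 21 with only the arrays compared and also without the 2 arrays of tumour 2 that stood apart.

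**Figure D2:**
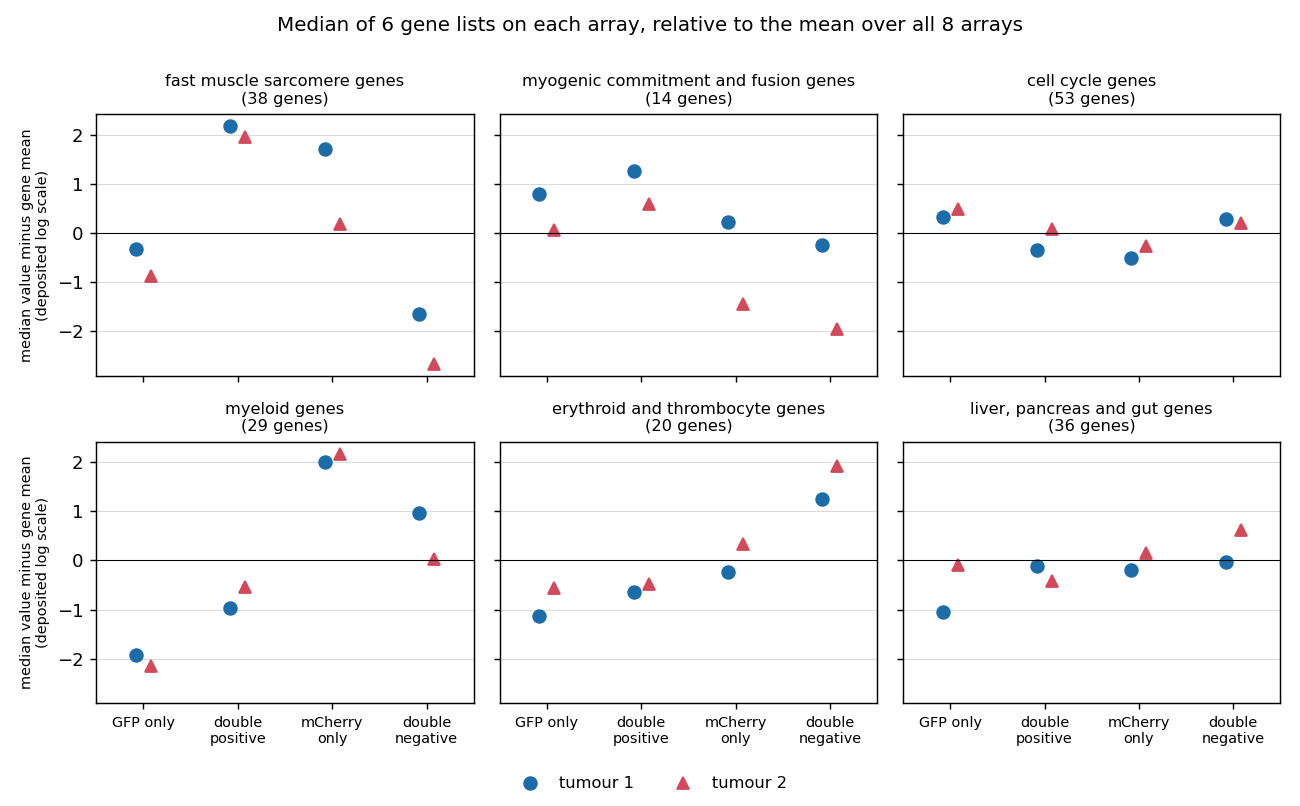
Median over the genes of 6 lists of the deposited log-scale value minus the gene's mean over all 8 arrays (vertical axis), in the 4 sorted populations (horizontal axis), with 1 point per tumour. The myeloid list lies at 2.00 and 2.16 in mCherry-only cells and at -1.92 and -2.15 in GFP-only cells, and the erythroid list is highest in double-negative cells at 1.25 and 1.93.

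Double-positive cells were compared with mCherry-only cells, which lack GFP. The largest called decreases in double-positive cells were in the integrin itgae.2 (-4.88 ± 0.70), the granulin gene grna.1 (-4.75 ± 0.62), the globin hbaa1 (-4.63 ± 0.73), the leukocyte phosphatase ptprc, also called CD45 (-4.55 ± 0.58), and shtn2 (-4.52 ± 0.54). Their adjusted p-values lay between 0.0276 and 0.0370. Of 29 myeloid genes 11 were lower (20 adjusted over the list alone), with a median of -3.36 (camera adjusted p = 4.73e-27). Its call held at adjusted p = 0.0473 with an estimated correlation, but not with the block as well (0.205). The erythroid list was lower with 1 of 20 genes called (2 adjusted over the list alone; median -0.40, adjusted p = 0.00870; adjusted p = 0.612 with an estimated correlation).

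Camera called the fast muscle, commitment, oxidative phosphorylation, ribosomal and RAS-MAPK lists higher in double-positive than in mCherry-only cells, with 0 members called by limma. It did not call the myogenic progenitor, slow and cardiac, and glycolysis lists. The fast muscle list had a median of 0.95 (adjusted p = 2.01e-05), the commitment list 1.37 (0.00177), the oxidative phosphorylation list 0.79 (2.87e-07), the ribosomal list 0.56 (2.69e-05) and the RAS-MAPK list 0.78 (0.0154). They had adjusted p = 0.612 with an estimated correlation, except the ribosomal list (0.617). At an unadjusted p under 0.05, 7, 4, 4, 1 and 5 of their genes were higher and 1 RAS-MAPK gene was lower. Adjusted over the list alone, 1 RAS-MAPK gene was higher. Without the mCherry-only array of tumour 2 the fast muscle, commitment, ribosomal, RAS-MAPK and erythroid lists lost their calls (adjusted p = 0.356, 0.356, 0.914, 0.0984 and 0.0907). The commitment list also did without the double-positive array of tumour 1 (0.207) and the RAS-MAPK list without that of tumour 2 (0.0895). The fast muscle, commitment, oxidative phosphorylation and ribosomal medians were 0.20, 0.52, 0.45 and 0.05 without the mCherry-only array of tumour 2. Without the pair of tumour 2 arrays that stood apart the fast muscle, commitment, ribosomal and erythroid calls ended (adjusted p = 0.357, 0.162, 0.999 and 0.0561), while the Notch and cell cycle lists, not called with all arrays (0.0813 and 0.171), were higher by camera (0.0188 and 0.0287). Without the dimmest 30% of probe sets camera also called the Notch list higher (0.0247) and the liver, pancreas and gut list lower (0.0300). The fit called 51 probe sets, 0 higher and 51 lower, which name 40 genes, and 580 were higher and 612 lower at an unadjusted p under 0.05. Including the block raised the calls to 133, 4 of them higher. The count was 0 without any 1 of the 6 arrays of the GFP-only, double-positive and mCherry-only populations and 105 without either double-negative array, so that the 5 genes named above were called in only 2 of these 8 runs (adjusted p up to 0.371 in the others). It was also 0 without the 2 arrays of tumour 2 that stood apart, and 84 without the dimmest 30% of probe sets.

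Double-positive cells were compared with double-negative cells, the populations with both reporters and with neither. Fast muscle genes were higher in double-positive cells, with pvalb2 at 7.78 ± 0.86, tnni2a.4 at 7.39 ± 0.72, the myosin light chain mylz3 at 7.11 ± 0.82, pvalb1 at 6.70 ± 0.71 and the troponin C gene tnnc2.2 at 6.67 ± 0.73. Phagocyte and erythroid genes were lower, with lyz at -8.13 ± 0.75, nt5c2l1 at -6.54 ± 0.60, hbaa1 at -6.25 ± 0.73 and the red cell anion exchanger slc4a1a at -5.59 ± 0.89. Also lower was susd3 (-5.75 ± 0.63), which is in neither the myeloid nor the erythroid list. The adjusted p-values of these genes lay between 0.00482 and 0.0279.

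Of 38 fast muscle genes 19 were higher in double-positive than in double-negative cells (30 adjusted over the list alone), with a median of 4.30 (camera adjusted p = 3.06e-50; adjusted p = 0.0699 with an estimated correlation). All 14 commitment and fusion genes had positive differences (median 2.09, adjusted p = 4.19e-09; adjusted p = 0.173 with an estimated correlation), with 0 called by limma and 8 at an unadjusted p under 0.05. Of 29 myeloid genes 5 were lower (9 adjusted over the list alone; adjusted p = 8.34e-14), and of 20 erythroid genes 6 were lower (10 lower and 1 higher adjusted over the list alone; adjusted p = 1.62e-14). Both lists had adjusted p = 0.0699 with an estimated correlation. Of the liver, pancreas and gut list 3 of 36 (9 adjusted over the list alone; adjusted p = 5.06e-08, and 0.146 with an estimated correlation) and of the lymphocyte list 1 of 9 (2 adjusted over the list alone; adjusted p = 0.00173, and 0.122 with an estimated correlation) were lower. The oxidative phosphorylation (median 0.85), RAS-MAPK (1.08) and heat shock lists (0.59) were higher and the cell cycle list lower (-0.20), with camera adjusted p-values of 2.49e-10, 0.00126, 0.00990 and 0.0130 and adjusted p = 0.521, 0.523, 0.565 and 0.523 with an estimated correlation. In these 4 lists 0 members were called by limma, and at an unadjusted p under 0.05 there were 2, 3, 7 and 0 higher and 0, 1, 2 and 2 lower, in that order, and 1 heat shock gene was higher when adjusted over the list alone. The RAS-MAPK and heat shock lists lost their calls without the double-negative array of tumour 2 (adjusted p = 0.908 and 0.389), the heat shock list also without the double-positive array of tumour 2 (0.0619), and the cell cycle list without the double-positive or double-negative array of tumour 1 (0.563 and 0.0805). The commitment, oxidative phosphorylation and RAS-MAPK medians were 1.06, 0.43 and 0.16 without the double-negative array of tumour 2. Without the pair of tumour 2 arrays that stood apart the RAS-MAPK and heat shock calls ended (adjusted p = 0.917 and 0.432), and camera called the slow and cardiac list higher (0.0148) and the ribosomal and fibroblast lists lower (0.0310 for both). The neural and glial list (median -0.41) had an adjusted p of 0.0538, 0.0394 with the block and 0.0428 with the mean of all probe sets of a gene.

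The fit called 84 probe sets between double-positive and double-negative cells, 37 higher and 47 lower, which name 63 genes. At an unadjusted p under 0.05, 411 were higher and 410 lower. Fitting the tumour as a block gave 165 calls, 74 higher and 91 lower. The count was 0 without either double-positive array, where the named genes had adjusted p-values up to 0.131 and slc4a1a up to 0.308, and 30 without the double-negative array of tumour 2 and 180 without that of tumour 1. Also without the double-negative array of tumour 2, slc4a1a was not called.

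The mCherry-only cells were compared with double-negative cells. Fast muscle genes were higher in mCherry-only cells, with pvalb2 at 7.27 ± 0.86, mylz3 at 6.63 ± 0.82, tnni2a.4 at 6.11 ± 0.72, tnnc2.2 at 5.94 ± 0.73 and pvalb1 at 5.79 ± 0.71, all with an adjusted p of 0.0122. Lower were lyz (-7.97 ± 0.75), the pancreatic proteases prss1 (-5.01 ± 0.52) and cela1.6 (-4.72 ± 0.53), the kinase pak1 (-4.44 ± 0.67) and the nucleosome-binding gene hmgn3 (-4.29 ± 0.71). The myeloid list went both ways: 5 of 29 myeloid genes were higher and 1, lyz, was lower (12 higher and 3 lower adjusted over the list alone). The median of that list was 1.34, and 0.83 without the double-negative array of tumour 2 (camera adjusted p = 4.89e-07; adjusted p = 0.219 with an estimated correlation).

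Of 38 fast muscle genes 8 were higher in mCherry-only than in double-negative cells (24 adjusted over the list alone; median 3.05, camera adjusted p = 1.48e-31; adjusted p = 0.219 with an estimated correlation). Of 20 erythroid genes 1 was lower (6 adjusted over the list alone; median -0.78, adjusted p = 1.91e-07; adjusted p = 0.219 with an estimated correlation), and of 36 liver, pancreas and gut genes 2 (10 adjusted over the list alone; median -0.02, adjusted p = 0.000858; adjusted p = 0.333 with an estimated correlation). The ribosomal (median -0.56, adjusted p = 9.13e-07) and cell cycle lists (-0.62, 5.29e-05) were lower and the heat shock list higher (0.36, 0.0163), each with 0 members called by limma and 0, 8 and 4 in that direction at an unadjusted p under 0.05, and 1 heat shock gene lower. They had adjusted p = 0.564, 0.316 and 0.555 with an estimated correlation. The ribosomal list lost its call without the mCherry-only array of tumour 2 (adjusted p = 0.659), and the heat shock and liver lists theirs without the mCherry-only array of tumour 1 (0.282 and 0.129) or the double-negative array of tumour 2 (0.672 and 0.0771), where the median of the liver list turned to 0.22. The fast muscle, erythroid and ribosomal medians were 2.02, -0.51 and -1.01 without the mCherry-only array of tumour 1, and the erythroid one -1.81 without the double-negative array of tumour 1. Without the pair of tumour 2 arrays that stood apart the ribosomal and heat shock calls ended (adjusted p = 0.0746 and 0.286), and camera called the slow and cardiac list higher (0.0111) and the fibroblast list lower (0.0136). The lymphocyte list, not called (adjusted p = 0.0800), was lower with the mean of all probe sets of a gene (0.000234). The commitment and fusion list (median 0.52) had an adjusted p of 0.0592, and 0.0219 with the block. The fit called 43 probe sets, 29 higher and 14 lower, which name 35 genes, and 576 were higher and 381 lower at an unadjusted p under 0.05. The blocked fit called 118, 82 of them higher. The fast muscle genes named for this comparison were no longer called without either double-positive array, although their differences did not change. The count was 0 without the mCherry-only array of tumour 1 or the double-negative array of tumour 2, 17 without the mCherry-only array of tumour 2, 5 without either double-positive array, 26 without either GFP-only array and 96 without the double-negative array of tumour 1. Where the count was 0 the adjusted p-values reached 0.0890 for mylz3 and 0.0740 for cela1.6, and pak1 and hmgn3 stayed called only without the double-negative array of tumour 1 (up to 0.188 and 0.266 in the other runs). It was 0 with only the arrays compared, where the smallest adjusted p among the named genes was 0.0521 for lyz, and 17 without the 2 arrays of tumour 2 that stood apart.

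GFP-only cells were also compared with the mean of the other 3 populations, the comparison closest to the question of the design text. The retinoic acid hydroxylase gene cyp26a1 was the 1 probe set called higher with all arrays (10 without the double-negative array of tumour 1), by 4.32 ± 0.66 (adjusted p = 0.0273). Lower were scinlb (-5.34 ± 0.46), hbaa1 (-5.19 ± 0.60), lcp1 (-4.56 ± 0.62), lgals3bp.1 (-4.56 ± 0.47) and srgn (-4.46 ± 0.55). Of 29 myeloid genes 11 were lower (19 adjusted over the list alone), with a median of -2.44 (camera adjusted p = 7.54e-36). The call was kept at adjusted p = 0.0275 with an estimated correlation, but not with the block as well (0.0776). The erythroid list was lower with 1 of 20 genes called (7 adjusted over the list alone; adjusted p = 1.33e-10, and 0.182 with an estimated correlation), and the fast muscle list with 1 of 38 (7 adjusted over the list alone; median -0.85, and -0.47 without the GFP-only array of tumour 2; adjusted p = 6.27e-10, and 0.279 with an estimated correlation).

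With 0 members called by limma, the cell cycle (median 0.51), RAS-MAPK (0.65), oxidative phosphorylation (0.34), ribosomal (0.33) and Notch lists were higher in GFP-only cells than in that mean by camera. Their adjusted p-values were 3.17e-05, 0.00303, 0.00214, 9.54e-05 and 0.00966, and 0.279, 0.499, 0.522, 0.522 and 0.219 with an estimated correlation, with 6, 2, 2, 1 and 5 genes higher at an unadjusted p under 0.05. The liver, pancreas and gut (median -0.63), endothelial (-0.64) and neural lists (-0.29) were lower with adjusted p-values of 6.18e-06, 0.0429 and 0.0434, and 0.279, 0.341 and 0.522 with an estimated correlation, with 0 called and 8, 0 and 1 lower at an unadjusted p under 0.05. Without the GFP-only array of tumour 1 the oxidative phosphorylation, ribosomal, endothelial and neural lists lost their calls (adjusted p = 0.141, 0.0517, 0.667 and 0.946) and the neural median turned to 0.08, and without the mCherry-only array of tumour 2 the first, the endothelial and the neural list did (0.0504, 0.0554 and 0.0975). The endothelial and neural lists also lost theirs without the double-positive array of tumour 1 (0.0775), and without the double-negative array of tumour 1 (0.0726) or 2 (0.203), respectively. Both were lost as well with quantile normalization (0.0786 and 0.124) and without the dimmest 30% of probe sets (0.103 for both). The liver median was -0.20 and -1.18 without the GFP-only array of tumour 1 or 2, and the RAS-MAPK median 0.41 without the double-negative array of tumour 2. Without the pair of tumour 2 arrays that stood apart the oxidative phosphorylation, ribosomal, endothelial and neural calls ended (adjusted p = 0.417, 0.184, 0.0882 and 0.417), and the glycolysis list, not called with all arrays (0.123), was lower by camera (0.0164). The commitment and fusion list (median 0.44) had an adjusted p of 0.115, and 0.0342 with the block. The fit called 42 probe sets, 1 higher and 41 lower, which name 34 genes, and 341 were higher and 566 lower at an unadjusted p under 0.05. With the block 79 were called, 2 of them higher. The count was 3 and 0 without the GFP-only array of tumour 1 or 2 and 26 and 18 without the double-positive array of tumour 1 or 2, and cyp26a1 stayed called only without either double-negative array (adjusted p up to 0.364 in the other runs). The 5 genes named as lower were not called without either GFP-only array (adjusted p up to 0.332), and srgn also not without the double-positive array of tumour 2 (0.0545).

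Whether the difference that goes with mCherry depends on GFP was tested as an interaction, (double-positive minus GFP-only) minus (mCherry-only minus double-negative). No gene passed: limma called 0 probe sets, with 162 higher and 194 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.117. With the tumour as a block it also called 0, with a smallest adjusted p of 0.0557. For lists, camera called 4 of 20. Such an interaction can also come from 1 population that differs from the others. Erythroid and thrombocyte genes had a median interaction of 1.84 (adjusted p = 8.11e-12; adjusted p = 0.289 with an estimated correlation; 8 of 20 higher when adjusted over the list alone) and liver, pancreas and gut genes one of 0.46 (adjusted p = 1.13e-05; adjusted p = 0.564 with an estimated correlation; 4 of 36 higher when adjusted over the list alone). The former median was 0.87 without the mCherry-only array of tumour 1 and 1.06 without the double-positive array of tumour 2. The latter lay between 0.01 (without the double-negative array of tumour 2) and 0.74 (without the mCherry-only array of tumour 2). Ribosomal protein genes had a median of 0.38 (adjusted p = 0.0138) and heat shock genes one of -0.56 (adjusted p = 0.0161), both with an adjusted p of 0.907 with an estimated correlation and 0 members at an unadjusted p under 0.05. The call of the ribosomal list was lost with quantile normalization (adjusted p = 0.184), and both were lost without the 2 arrays of tumour 2 that stood apart (adjusted p = 0.874 and 0.223), where fast muscle genes had a negative interaction by camera (0.000949; 0.493 with all arrays). The lymphocyte list, not called (adjusted p = 0.213), was higher with the mean of all probe sets of a gene (0.00114). Of the 8 runs that left out 1 array, 4 ended the ribosomal call (without the double-positive or double-negative array of tumour 1 or the GFP-only or mCherry-only array of tumour 2, adjusted p up to 0.566) and 4 the heat shock call (without the GFP-only, double-positive or mCherry-only array of tumour 1 or the double-negative array of tumour 2, up to 0.664).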

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

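All tests of explanations reported here, and the counts without 2 arrays of tumour 2, were chosen after the results had been seen. Bootstrap SEs, here and in the later sections, come from resampling the genes of a list. They measure the spread between genes and not the spread between tumours or arrays.

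In the interaction test camera called 4 gene lists. The medians over (double-positive minus GFP-only) minus (mCherry-only minus double-negative) were 1.84 for erythroid and thrombocyte genes, 0.46 for liver, pancreas and gut genes, 0.38 for ribosomal protein genes and -0.56 for heat shock and dissociation stress genes. With an estimated correlation 0 of these 4 lists were called by camera (adjusted p = 0.289, 0.564, 0.907 and 0.907). Relative to each gene's mean over all 8 arrays, the erythroid median was 1.25 and 1.93 in double-negative cells of the 2 tumours. It was -1.14 and -0.57 in GFP-only, -0.64 and -0.48 in double-positive and -0.23 and 0.34 in mCherry-only cells. The interaction of the erythroid list thus follows its high level in double-negative cells. Leaving out 1 array kept the erythroid and the liver, pancreas and gut calls in 8 of 8 runs and each of the other lists' calls in 4 of 8, although the liver, pancreas and gut median was 0.01 without the double-negative array of tumour 2.

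The source of the blood-cell and pancreas transcripts that were lower in GFP-only cells is not known. The blood-cell transcripts may come from host cells in the mCherry-only and double-negative fractions, or from tumour cells that express them. The pancreas transcripts may likewise come from host or tumour cells, but were high only in double-negative cells. For example, prss1 had a mean of 8.73 there, 3.72 in mCherry-only and 3.82 in GFP-only cells. The tests that follow did not cover the pancreas genes. The mCherry-only fraction was sorted on its reporter in repeated rounds, but the purity of the fractions was not examined here. The next test compares lists whose levels had already been seen, and its bootstrap SE does not measure the spread between tumours. It bears only on a mix of other cells shared by both fractions. Host cells mixed differently in the mCherry-only and double-negative fractions stay open. A lower share of tumour cells with the same mix of other cells in both fractions is argued against, since the median mCherry-only minus double-negative differences of the myeloid and erythroid lists lay 1.92 (bootstrap SE 0.76) apart in tumour 1 and 2.12 (SE 0.88) apart in tumour 2, and so is 1 aberrant mCherry-only array, since 14 and 12 myeloid genes were still called lower with the mCherry-only array of tumour 1 or 2 left out. RNA of myeloid cells in the mCherry-only fraction cannot be told apart from expression by the tumour cells of that fraction: 86.2% of the measured myeloid genes (25 of 29) were higher there than in GFP-only cells in both tumours, but this restates the pattern, and 26 were higher in double-negative and 17 in double-positive cells. Among the measured myeloid genes, the brightest in that fraction were cd74a, lgmn and cd74b, with means of 11.41, 10.93 and 10.11. They also had means of 8.73, 7.98 and 7.71 in GFP-only and 9.51, 8.67 and 8.77 in double-negative cells. The next brightest, lgals3bp.1 and marco, had means of 9.995 and 9.79 in mCherry-only cells. Their means were only 2.655 and 2.625 in GFP-only and 5.35 and 5.24 in double-negative cells. Whether the tumour cells of the sorted populations themselves differ in the blood-cell and pancreas transcripts was not tested and stays open.

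The mCherry-only and double-negative arrays of tumour 2 stood apart from the other 6 in their rank correlation with the GFP-only and double-positive arrays. This measure takes the GFP-carrying populations as its reference, so it cannot say which tumour's double-negative array is the unusual one. In tumour 1 the double-negative array was close to the GFP-only array (median absolute difference 0.40, r = 0.909). In tumour 2 these values were 0.66 and 0.737. A monotone difference of scale between arrays is argued against, since it would leave rank correlations unchanged, and the mean rank correlation with the GFP-only and double-positive arrays was lower than in tumour 1 by 0.157 for mCherry-only and 0.196 for double-negative cells. Less RNA of muscle-lineage tumour cells on these arrays cannot be told apart from other losses of signal: the myogenic commitment genes were lower by a median of -0.83 (bootstrap SE 0.40) beyond their tumour difference in the other populations, but so were RAS-MAPK (-1.24, SE 0.31), oxidative phosphorylation (-0.66, SE 0.09) and ribosomal protein genes (-0.53, SE 0.03). By the same measure fast muscle (-0.57, SE 0.19), heat shock (-0.45, SE 0.19) and glycolysis genes (-0.325, SE 0.13) were lower as well. Fast muscle and heat shock genes differed between the arrays. Compared with tumour 1, fast muscle genes were lower by -1.60 in mCherry-only cells but by only -0.48 in double-negative cells. Their change was -0.71 in GFP-only and -0.175 in double-positive cells. Heat shock genes were lower by -0.65 in double-negative cells but by only -0.09 in mCherry-only cells. Their change was -0.21 in GFP-only and 0.30 in double-positive cells. RAS-MAPK genes were lower mainly in double-negative cells (-1.64, against -0.51 in mCherry-only cells). The erythroid list was higher by only 0.51 (SE 0.32) beyond the other populations, and the myeloid list was lower by -1.16 (SE 0.42) in double-negative cells of tumour 2 than of tumour 1. RNA quality was not measured and stays open, and so does a difference between the tumours, since each has 1 array per population.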

How the results depend on the processing

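The alternatives were fixed before the data were examined, except for leaving out 2 arrays of tumour 2 together. With the tumour as a replicate block the counts of called probe sets were 248 for GFP-only against mCherry-only, 121 against double-negative, 18 against double-positive and 79 against the mean of the others, 133 for double-positive against mCherry-only, 165 for double-positive against double-negative and 118 for mCherry-only against double-negative. All probe sets called without the block were called with it. The block kept 70 of 70 calls of named genes and 64 of 64 of lists at the preset correlation, and gained 10 and 3. It ended the calls of the myeloid list with an estimated correlation (adjusted p between 0.0776 and 0.205) and, beyond the values printed beside each result, changed no other call. Quantile normalization gave 0 calls for GFP-only against double-positive. Without the dimmest 30% of probe sets, double-positive against mCherry-only had 84. With only the arrays compared, GFP-only had 18 calls against double-negative and 21 against double-positive, and mCherry-only against double-negative had 0. Without the 2 arrays of tumour 2, these counts were 46, 21 and 17, and double-positive against mCherry-only had 0. With an estimated correlation, 4 of 64 list calls remained, all of the myeloid list. The cause of these changes was not tested. The other counts stayed within 1.5 times of the reported ones, and a minimum fold of 2 changed none.

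Leaving out each of 8 arrays in turn, the counts ranged from 43 to 183 for GFP-only against mCherry-only, 11 to 174 against double-negative, 0 to 3 against double-positive and 0 to 61 against the mean of the others. They ranged from 0 to 105 for double-positive against mCherry-only, 0 to 180 for double-positive against double-negative and 0 to 96 for mCherry-only against double-negative, and were 0 for the interaction. List calls ranged from 57 to 76. Over the 560 called values of named genes in these runs, 366 kept the call, 194 lost it and 0 turned. Of 512 list values, 456 kept it, 55 lost it and 1 turned in the direction of the test: the median interaction of ribosomal protein genes was -0.10 without the mCherry-only array of tumour 2 (adjusted p = 0.395) and 0.90 without that of tumour 1. With that one, 5 of the 512 medians changed sign, the other 4 in lists that lost their calls (neural and glial, and liver, pancreas and gut genes). In all 8 runs lgals3bp.1, marco, c1qc, scinlb, hbaa1, rgs2, fgl2a, slc7a7, itgae.2, ctss2.2 and cxcr4b stayed called between GFP-only and mCherry-only, and lyz, hbaa1, scinlb, nt5c2l1 and coro1a between GFP-only and double-negative. Amylase amy2a lost its call in each run (adjusted p between 0.0707 and 0.326). Of named genes, quantile normalization ended the calls of dhrs3a (adjusted p = 0.0536), pfkma (0.0578), pvalb4 against double-positive (0.119) and hmgn3 (0.0519), and the trend ended that of klf1 (0.0615) and gained mylpfa (0.0492). With only the arrays compared, 43 of 64 calls of named genes were kept and 9 gained. Without the 2 arrays of tumour 2, 57 of 70 calls of named genes and 42 of 64 of lists were kept, and 10 of each were gained. Quantile normalization kept 59 of 64 list calls, and leaving out the dimmest probe sets 58 of 62 (3 gained). The mean of all probe sets of a gene gained 4. Results uncalled under both settings were counted as alike whatever their sign. The median of all probe sets shifted by less than 0.1 in every comparison. Signal over background was not measured here, so its limit on dim genes is unknown.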

Other observations

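The genes of the next paragraph were chosen after their values were seen, and so was the test of retinoic acid genes.

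Probe sets of the T-cell genes trac and tox were among those lower in mCherry-only than in double-negative cells. The T-cell receptor constant chain gene trac fell by a log2 difference of -5.65 ± 0.75 (adjusted p = 0.0195) and tox, a regulator of T-cell development, by -5.41 ± 0.74 (adjusted p = 0.0201), each on a probe set with a lower mean than the gene's brightest one. Their brightest probe sets were not called, with an adjusted p of 0.999 for both. The result for the lymphocyte list of 9 genes depended on how probe sets are combined. Camera gave it an adjusted p of 0.0800 with the brightest probe set and 0.000234 with the mean of all probe sets of a gene. Whether trac and tox account for this was not tested. Both calls were lost without the mCherry-only array of tumour 1 (adjusted p = 0.131 for trac and 0.139 for tox), the double-negative array of tumour 2 (0.101 and 0.105) or either double-positive array (0.0710 and 0.0589), and that of tox also without the mCherry-only array of tumour 2 (0.0811). With only the arrays compared, 0 probe sets were called by limma in this comparison. Which cells these transcripts come from was not tested.

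The retinoid genes cyp26a1 and dhrs3a are known to be induced by retinoic acid, and both were higher in GFP-only than in mCherry-only cells, by 5.63 and 4.59. A higher retinoic acid response in GFP-only cells could raise both. The other retinoic acid response genes measured had a median difference of -0.25 (bootstrap SE 0.23), with 8 of 18 higher and 0 called by limma, so this test cannot tell. The bound first set counted any median under 1 as evidence against the explanation and was changed, after the value had been seen, to a median more than 2 SE below 0. Under the first bound the value would have argued against it. Of the 18, the retinoic acid hydroxylase genes cyp26b1 and cyp26c1 were at 0.01 and -0.39, neither of them called.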
